A study of Mus musculus with 12 samples.

How the data were processed

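Gene expression was measured with the NanoString nCounter Mouse Immunology panel, in which barcoded probe pairs hybridize to RNA and are counted without amplification, in 12 samples from 12 mice that the labels number separately. The samples form 4 groups of 3: spleen and mesenteric lymph nodes, each from ampicillin-treated and from untreated mice. Per the labels' protocols, tissues were kept in RNAlater and RNA was isolated with an RNeasy kit. The submitters' design text states normalization to 14 housekeeping genes in nSolver, a fold change over 1.25 and a level of 0.05 for calling genes.

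The deposited table held whole-number counts for 561 genes, of which 14 were the housekeeping genes. These values did not carry the normalization that the design text names. The lowest value in each sample was 1, the first whole number missing from any sample was 18 or higher, totals ran from 396950 to 738489 counts, and the housekeeping geometric mean ran from 912.4 to 1501 counts, a 1.65-fold range. The values were therefore treated as unnormalized counts. A further deposited table with control probes had 12 columns whose names matched no sample label, so it was not used and no background was taken from its control probes.

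Counts of each sample were divided by a factor from the geometric mean of its 14 housekeeping genes. The design text gives only their number, and the 14 genes used here were named from knowledge of this panel type. Of the 547 other genes, 445 with a mean of at least 20 scaled counts were tested and 102 below that were left out. The minimum of 20 was set before the data were examined. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with a model of 4 group means over all 12 samples, 8 residual degrees of freedom and Benjamini-Hochberg adjustment over the 445 genes in each contrast. A gene was called at an adjusted p under 0.05. The design fixed before the data were examined had named limma 3.58.1 on log2 values, because the values were labelled as normalized. The count test took its place because the values turned out to be counts, and limma became an alternative. Log2 changes are given with their standard error (SE), and levels as scaled counts with the SD over 3 samples. The SE and p rest on a spread per gene estimated over all 4 groups together, so they do not measure the spread of a single group.

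The 5 contrasts were ampicillin against control in spleen, the same in lymph nodes, the difference of these effects, their mean, and lymph nodes against spleen in control mice. For gene lists, 25 lists of cell types and pathways were fixed before the data were examined; 23 had at least 4 tested genes. Each was tested with camera from limma at a preset correlation of 0.01, which asks whether the list moved relative to the other genes, and again with an estimated correlation and with fry. Where a group mean lay below 20 counts, the change is given as a lower bound, the brighter group's mean divided by 20. Named genes followed a rule fixed beforehand. In each ampicillin comparison they were all called genes, or the 12 largest rises and 12 largest falls where more than 24 were called. Where fewer than 20 were called, genes of the smallest unadjusted p filled the number to 20. For the difference they were the called genes, or else the 5 of smallest p, for the mean the 10 called genes of smallest p, and for the tissues the 10 largest called changes each way. The 3 members with the largest change of each called list were added. Some genes outside this rule also appear, and some genes that the rule names are not reported here.

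Gene names are those of the table. Against the mouse reference gene table of assembly GRCm38.p6, 545 were current symbols, 14 matched 1 synonym and 2 matched none. No genome build is named for the probes, so no coordinates are given. Probes for near-identical families such as Klra and H2 genes may hybridize to several members, and those values are uncertain.

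The count test was tested on simulated data with 200 of the 445 genes changed. In the spleen contrast it recovered 32.8% of genes changed 1.25-fold, 83.6% changed 1.5-fold and 93.9% changed 2-fold. In the lymph node contrast these shares were 32.8%, 79.1% and 90.9%, and in the difference of effects 10.4%, 34.3% and 89.4%. The simulated genes varied independently, with the same dispersion in all groups and no outlying sample. With 200 genes changed, the adjusted threshold is also more lenient than where few genes change. These shares are therefore not the power in the real data, which can be lower. Counts of each pair of replicates differed beyond counting noise, by 3.59 to 66.1 times the chi-square expected per degree of freedom, so all 12 samples were kept as separate replicates. Sample titles share the numbers 1 to 3 across groups, but the labels name different mice, and the numbers were not used as pairs.

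Alternatives included trimmed mean (TMM) scaling, scaling to the median of tested genes, quantile normalization, no scaling, other pseudocounts and filters, robust empirical Bayes, DESeq2 1.42.0, limma with and without sample weights, the methods' t-test that the design text names, and leaving out each sample. Figures were drawn with matplotlib 3.10.9.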

Results

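The series measured immune gene expression in spleen and mesenteric lymph nodes, the nodes that drain the gut, of mice with hemophilia A, a bleeding disorder caused by loss of clotting factor VIII. Mice on a C57BL6 background were either given the broad-spectrum antibiotic ampicillin by gavage when 3 weeks old or left untreated, and tissues were taken at 6 weeks. Each of the 4 groups held 3 samples. No group is described as given gavage without ampicillin, so an effect of gavage cannot be told from one of ampicillin. The total count per sample averaged 654278 ± 77401 in control spleen, 557202 ± 137394 in ampicillin spleen, 550835 ± 99034 in control nodes and 457656 ± 79471 in ampicillin nodes (SD, n = 3 each). The 10 most abundant genes took 39.9% to 43.2% of the counts of a sample. The knocked-out clotting factor gene was not analysed here.

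The first comparison asked how ampicillin exposure was reflected in the spleen. The largest rises were those of genes of the erythroid lineage. Tfrc, the transferrin receptor that brings iron into red cell precursors, rose 3.99-fold (log2 change 2.00, SE 0.51, adjusted p = 0.026, edgeR), from 806.4 ± 280.5 to 3227 ± 2345 scaled counts (SD, n = 3 each). Tal1, a transcription factor of blood cell precursors, rose 4.40-fold (adjusted p = 0.038). Abcb10, a mitochondrial transporter of erythroid cells, rose 4.41-fold (adjusted p = 0.025), and Icam4, a red cell adhesion molecule, 5.39-fold (adjusted p = 0.040). The high values lay in 2 of the 3 ampicillin spleens, a spread that the SE and p, shared over the 4 groups, do not measure. Ampicillin spleen 1 differed from spleens 2 and 3 by 43.0 and 66.1 times the chi-square expected per degree of freedom. Ampicillin spleens 2 and 3 differed from each other by 11.3 times, pairs of control spleens by 6.99 to 15.5 times and pairs of node replicates by 3.59 to 6.92 times. Tfrc stood at 609, 5132 and 3941 scaled counts in ampicillin spleens 1, 2 and 3, against 774, 1102 and 544 in the controls. With 1 sample left out at a time, Tfrc and Abcb10 passed in 7 of 12 fits, Tal1 in 5 and Icam4 in 3, and none of these genes passed without ampicillin spleen 2, ampicillin spleen 3 or any 1 of the control spleens. The 12 fits, here and below, include those that leave out a node sample. Such fits keep all spleens and change little but the shared spread, so passing them says little about single spleens. The log2 change of Icam4 was 1.78 without ampicillin spleen 2 and 3.00 without ampicillin spleen 1, and that of Tal1 1.55 and 2.66. The list of platelet and erythroid genes had 3 of 7 tested members higher and none lower. Adjusted over the list alone 3 were higher and 1 lower, and the list did not pass (adjusted p = 0.063, camera).

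Ccrl2, a receptor-like protein that binds chemerin, rose 2.69-fold from 44.6 ± 3.89 to 121.5 ± 52.2 scaled counts (adjusted p = 0.017), and all 3 ampicillin spleens lay above all controls. Cd24a, a surface protein of developing B and erythroid cells, rose 2.39-fold (adjusted p = 0.046) and stood at 1016, 5479 and 4196 scaled counts in ampicillin spleens 1, 2 and 3. Fkbp5, a co-chaperone induced by glucocorticoids, rose 1.64-fold (adjusted p = 0.038). Cebpb, a transcription factor of myeloid cells, rose 1.52-fold (adjusted p = 0.028), and Cd34, a marker of progenitors and endothelium, 1.49-fold (adjusted p = 0.040). C1qbp, a mainly mitochondrial protein that can bind complement C1q, rose 1.23-fold (adjusted p = 0.020). With TMM scaling Tal1, Icam4 and Cd24a did not pass (adjusted p = 0.055, 0.066 and 0.066). With 1 sample left out at a time, Ccrl2 passed in 10 of 12 fits, C1qbp and Cebpb in 8, Cd34 and Fkbp5 in 5, and Cd24a in 1, the fit without ampicillin spleen 1.

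T cell genes fell in the ampicillin spleen. Of 19 tested T cell genes 8 fell and none rose, 11 fell when adjusted over the list alone, and 4 fell with TMM scaling. The list passed camera (adjusted p = 0.0011; adjusted p = 0.95 with an estimated correlation), also with TMM scaling (adjusted p = 0.00016). Cd6 and Cd5, surface regulators of T cell receptor signalling, had log2 changes of -0.69 ± 0.14 and -0.62 ± 0.12 (SE; adjusted p = 0.017 for both). Cd3d and Cd247, chains of the T cell receptor complex, had changes of -0.61 and -0.60 (adjusted p = 0.038 and 0.037). With 1 sample left out at a time, Cd6 and Cd5 passed in 10 of 12 fits, Cd247 in 5 and Cd3d in 4. The list lay at a median of -0.42, which is -0.25 relative to the median of all tested genes. Per library, its mean log2 level above the panel mean was 0.97, 0.61 and 0.43 in ampicillin spleens 1, 2 and 3, and 0.88 to 1.03 in controls. Ampicillin spleens 2 and 3 were also those with high erythroid genes.

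Further falls included Foxp3, the transcription factor of regulatory T cells, by 0.63 (log2, adjusted p = 0.038), Tnfrsf4 by 0.69 (adjusted p = 0.017) and Folr4 by 0.60 (adjusted p = 0.020). Of 11 regulatory T cell genes 3 fell, 4 when adjusted over the list alone, and the list did not pass (adjusted p = 0.14). Lta, a lymphotoxin needed for lymphoid structure, fell by 0.63 (adjusted p = 0.0135). The cytokine gene Tnf fell by 0.67, the chemokine receptor gene Cxcr6 by 0.64, Slamf1 by 0.61, and Xcr1, a receptor of cross-presenting dendritic cells, by 0.75. Of the 12 fits without 1 sample, Lta passed in 11, Tnfrsf4 in 9, Xcr1 in 8, Folr4 and Cxcr6 in 7, Slamf1 in 6, Foxp3 in 4 and Tnf in 3.

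**Figure D1:**
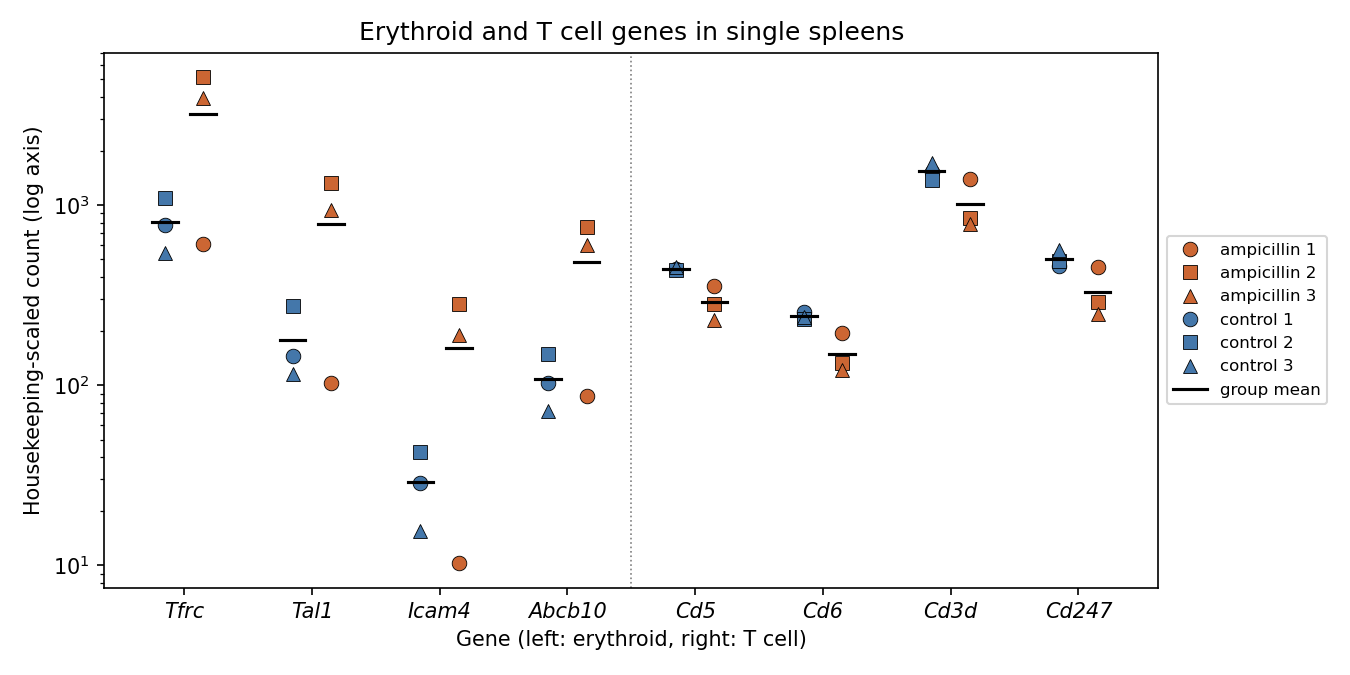
Housekeeping-scaled counts (log axis) of 4 erythroid and 4 T cell genes in each spleen; blue points are controls, orange points ampicillin samples, symbols the replicate number and bars the group mean of 3. Tfrc reached 5132 and 3941 in ampicillin spleens 2 and 3 and 609 in spleen 1, and all ampicillin values of Cd5 lay below all control values.

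B cell genes also fell. Of 11 tested members 3 fell, among them Cd79a by 0.53 and Cd22 by 0.50 (log2), and 9 fell when adjusted over the list alone. The list passed (adjusted p = 0.049; adjusted p = 0.95 with an estimated correlation) but not with TMM scaling (adjusted p = 0.13). The complement list was higher relative to the panel (adjusted p = 0.0099; adjusted p = 0.95 with an estimated correlation). Its own median log2 change was 0.05, against -0.17 for all tested genes. Tested against no change rather than against other genes, the complement list did not pass (adjusted p = 0.69, fry). Of its 16 members 1 rose, C1qbp, and 1 fell, Cd55, which limits complement activation on host cells (log2 change -0.39), and the same counts held when adjusted over the list alone. With TMM scaling Cd55 did not pass (adjusted p = 0.091), and 2 members of the list were higher and 0 lower. Cfd, a complement factor, was at least 1.48-fold higher and did not pass. It stood at 70.6 scaled counts in ampicillin spleen 3 and at 8.92 to 10.9 in the other spleens.

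The neutrophil list was higher relative to the panel (adjusted p = 0.049; adjusted p = 0.58 with an estimated correlation) but not with TMM scaling (adjusted p = 0.16). Its median log2 change was -0.0020 and its mean 0.06. Per library, its mean log2 level relative to the panel mean was -0.02, 0.46 and 0.60 in ampicillin spleens 1, 2 and 3. In control spleens it was 0.03 to 0.41, so ampicillin spleen 1 lay below all controls. Of 9 members 1 rose, Cebpb, also when adjusted over the list alone, while Camp (-0.44 ± 0.44) and Il1r2 (0.38 ± 0.24) did not pass. The 4 passing lists became 2 without ampicillin spleen 1, ampicillin spleen 2 or control node 3, and 1 without control spleen 1.

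Altogether 75 of 445 genes were called in spleen, 10 higher and 65 lower, with the median of all tested genes at -0.17. TMM scaling, which put that median at 0.00063, called 22 genes, 11 higher and 11 lower, and 18 genes were called with both. Of the 12 largest falls 4 passed with both scalings, Tnfrsf4, Cd6, Lta and Cd5, as did 7 of the 10 rises. The groups did not overlap in 34.6% of genes with housekeeping scaling, where chance gives 10% for a single gene. Genes vary together within a sample, so the share over all genes varies widely between random splits. It was not computed over splits, and its excess over 10% was not tested. At an unadjusted p under 0.05 there were 158 genes. A fit of the 6 spleens alone with edgeR called 0 genes in place of 75, with 122 at an unadjusted p under 0.05. On all samples the test fixed beforehand, limma on log2 values, called 64 genes, 4 higher and 60 lower. With robust empirical Bayes edgeR called 65, 5 higher and 60 lower, so fewer than the 10 rises passed with either. DESeq2 called 95 genes with housekeeping size factors, 10 higher and 85 lower, and 54 with its own, 25 higher and 29 lower. The count was 159 without ampicillin spleen 1, 4 without ampicillin spleen 2 and 17 without ampicillin spleen 3. It was 0, 12 and 32 without control spleens 1, 2 and 3, and 44 and 46 without control nodes 2 and 3.

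The same question in the mesenteric lymph nodes gave 2 called genes. Cxcl13, the chemokine that draws B cells into follicles, rose 1.65-fold, from 1340 ± 225 to 2208 ± 67.7 scaled counts (SD, n = 3; log2 change 0.72, SE 0.13, adjusted p = 0.015, edgeR). Map4k2, a kinase of stress-activated signalling, fell by 0.47 on the log2 scale (SE 0.07, adjusted p = 0.0093), from 687.8 ± 21.3 to 497 ± 30.4 scaled counts. It was the 1 gene called in both tissues. Several genes of cytokine and NF-kB signalling did not pass (adjusted p = 0.094 each). Among them Jak3 stood at -0.57 ± 0.14, Socs3 at -0.55 ± 0.15, Stat5a at -0.34 ± 0.08 and Ikbke at -0.50 ± 0.14 (log2 change and SE). Chuk stood at -0.41 ± 0.10, Nfkbiz at -0.44 ± 0.11 and Traf1 at -0.36 ± 0.10. At the same adjusted p were Tap1 (-0.44), Notch1 (-0.39), Cd5 (-0.42), Casp8 (-0.30), Spn (-0.31) and Tlr1 (-0.37). With values above 0 were Il22ra2, a soluble receptor that binds interleukin 22 (0.69 ± 0.19), Bst1 (0.52), Ly96 (0.47), Ccl9 (0.46) and Cd9 (0.30). With TMM scaling all of these genes that missed the threshold passed (adjusted p = 0.030 to 0.046) except Spn and Tlr1 (adjusted p = 0.063 each).

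The complement list was higher relative to the panel in the nodes (adjusted p = 0.046, camera; adjusted p = 0.91 with an estimated correlation), at a median of 0.19. None of its 16 members passed over all genes or adjusted over the list alone. C7 stood at 0.39, Cfd at -0.28 and C6 at -0.28. No list passed in nodes without ampicillin spleen 2, ampicillin node 2, control node 1 or control node 3. The T cell list, at a median of -0.18, did not pass, nor did the neutrophil and the monocyte and macrophage lists, at medians of 0.35 and 0.14 (adjusted p = 0.065 each, camera). Without genes below background in both groups, which the test included, the medians of the neutrophil and the monocyte and macrophage lists were 0.26 and 0.14. At an unadjusted p under 0.05 there were 88 genes. TMM scaling called 32 genes, 18 higher and 14 lower, and DESeq2 called 22 with housekeeping size factors and 44 with its own. The groups did not overlap in 31.0% of genes, where chance gives 10% for a single gene, and this excess was not tested over splits either. The count of 2 became 0 without ampicillin node 1, control node 1 or control node 3, and 1 without ampicillin node 2. It became 4 without ampicillin node 3, 6 without control node 2 and 32 without ampicillin spleen 1.

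**Figure D2:**
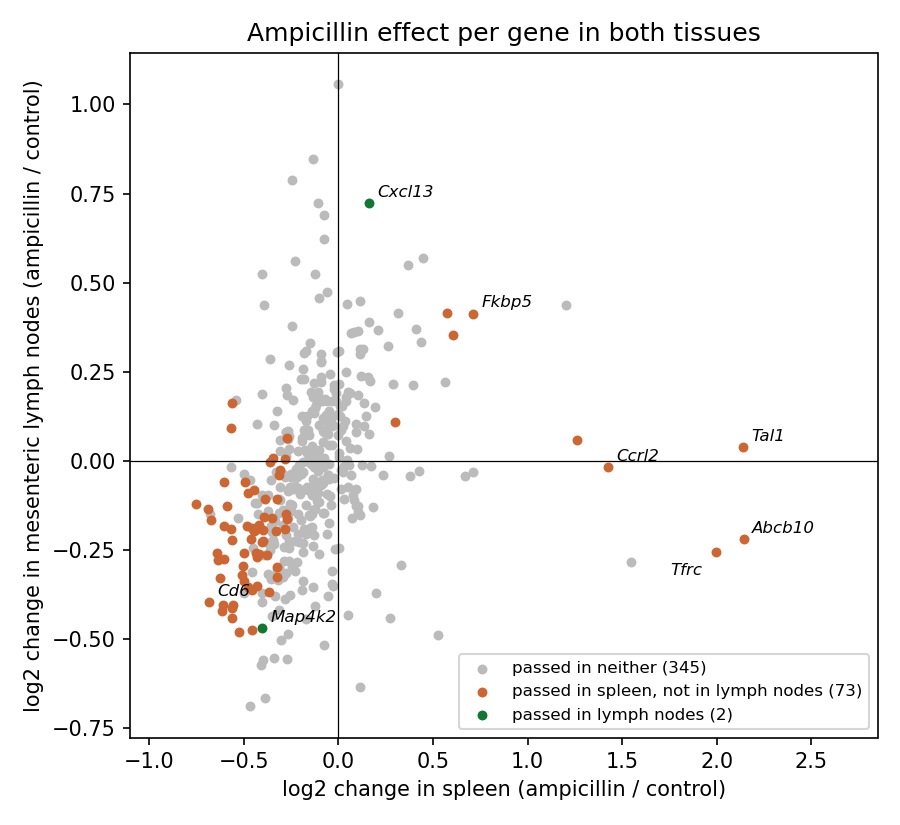
Log2 change with ampicillin per tested gene in spleen (x axis) against lymph nodes (y axis), without genes below background in both groups of a tissue; orange points passed in spleen and not in lymph nodes, green points in lymph nodes, grey points in neither. Cxcl13 lies at 0.72 in lymph nodes, and Abcb10 lies at 2.14 in spleen.

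Whether the ampicillin effect differed between the tissues was tested as the effect in lymph nodes minus that in spleen. edgeR called 0 genes, with 49 at an unadjusted p under 0.05, and DESeq2 also called 0. The 5 genes of smallest p did not pass (adjusted p = 0.31 each). They were Cd9 (0.49 ± 0.12), Sh2d1a (0.66 ± 0.17), Casp1 (0.44 ± 0.12), Ms4a1, the B cell gene for CD20 (0.48 ± 0.14), and Ccrl2 (-1.44 ± 0.43, log2 and SE). Without ampicillin spleen 1 the count was 59. The list of genes of MHC class II, which presents antigen to helper T cells, was higher relative to the other genes in this difference (adjusted p = 0.042, camera; adjusted p = 0.98 with an estimated correlation). Tested against no change rather than against other genes it did not pass (adjusted p = 0.395, fry). Of its 8 members 0 were called over all genes and 5 when adjusted over the list alone. In spleen its median was -0.30 and 1 member, H2-DMa, outside the naming rule in spleen and chosen after its values were seen, fell by 0.35, against 7 adjusted over the list alone and 0 with TMM scaling. In nodes the median was 0.04 and none passed. In the same difference 11 of 11 B cell genes lay above 0, at a median of 0.16, and so did 17 of 19 T cell genes, at a median of 0.23, with the median of all tested genes at 0.13. No list passed camera for the difference without ampicillin spleen 2, ampicillin nodes 2 or 3, control spleen 1 or control node 3.

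Averaged over both tissues, 102 genes changed with ampicillin, 13 higher and 89 lower. With TMM scaling 97 did, 53 higher and 44 lower, and 57 genes were called with both. The 10 of smallest p all fell, with both scalings. Map4k2 fell by 0.43 (log2, adjusted p = 0.00048) and the antigen transporter gene Tap1 by 0.50 (adjusted p = 0.0048). The T cell genes Cd5, Cd6, Cd27 and Icos fell by 0.52, 0.54, 0.48 and 0.39. Traf1 fell by 0.41, Lta by 0.46, the B cell receptor component Cd79a by 0.50 and the interferon-regulated transcription factor gene Irf1 by 0.38. Without ampicillin spleen 1 the count was 157, and without control node 1 it was 67.

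Across the 445 genes, which are not independent replicates, the effects in spleen and nodes had a Pearson correlation of 0.27 (exact permutation p = 0.02, two-sided, over 100 relabellings). The Spearman correlation was 0.45 (exact permutation p = 0.01, the smallest possible). Of the 65 genes that fell in spleen, 60 (92.3%) had a value below 0 in nodes, against 60.2% of all tested genes. With TMM scaling 56 of the same genes (86.2%) did, against 49.0% of all. Of the 10 that rose 6 had a value above 0, and 8 with TMM scaling.

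The last comparison set lymph nodes against spleen in untreated mice. T cell genes were higher in lymph nodes. Of 19 members 17 were higher and 1, Cd7, outside the naming rule and chosen after its values were seen, was lower, the same when adjusted over the list alone (camera adjusted p = 2.0e-05; adjusted p = 0.93 with an estimated correlation). Cd3e was 2.45-fold higher, and the transcription factor gene Lef1 and the kinase gene Zap70 were 2.35-fold and 2.34-fold higher. All 11 B cell genes were lower, also over the list alone (adjusted p = 0.0019; adjusted p = 0.93 with an estimated correlation). Cr2, the complement receptor of B and follicular dendritic cells, had a log2 change of -1.55 ± 0.13 (SE), Ms4a1 of -1.15 ± 0.10 and Blnk of -0.92 ± 0.09. Of 20 monocyte and macrophage genes 16 were lower and 2 higher, the same over the list alone (adjusted p = 0.00019; adjusted p = 0.93 with an estimated correlation). Cd163, a hemoglobin scavenger receptor, was at least 17.5-fold lower and the Fc receptor gene Fcgr4 had a log2 change of -3.78, while the scavenger receptor gene Msr1 was 8.41-fold higher.

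Of 9 neutrophil genes 8 were lower in nodes and 1 higher, the same when adjusted over the list alone (adjusted p = 0.0070; adjusted p = 0.23 with an estimated correlation). S100a8 and S100a9, the calprotectin subunits, were at least 335.7-fold and at least 291-fold lower, and Camp, an antimicrobial peptide gene, at least 55.7-fold. Of 7 platelet and erythroid genes 4 were lower and 1 higher, the same over the list alone (adjusted p = 0.023; adjusted p = 0.93 with an estimated correlation). That list did not pass with TMM scaling (adjusted p = 0.061). The platelet genes Ppbp and Gp1bb were at least 188-fold and at least 10.6-fold lower, and Tal1 had a log2 change of -2.12 ± 0.72. Ccr3 and Ctsg were at least 12.4-fold and at least 3.09-fold lower, and Il1b had a log2 change of -2.79.

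Among the genes higher in nodes were the chemokine genes Ccl22 (18.2-fold), Ccl2 (7.45-fold), Ccl8 (at least 5.13-fold) and Ccl11 (at least 5.79-fold). The C-type lectin gene Cd209g was 13.8-fold higher, the alarmin gene Il33 6.20-fold and Tnfsf11, which encodes RANKL, 4.92-fold. Vtn was at least 7.02-fold higher and Cfd, which is abundant in fat, at least 8.82-fold. In total 285 genes were called, 132 higher and 153 lower, and 281 were shared with TMM scaling, which called 302. The groups did not overlap in 75.3% of genes, where chance gives 10% for a single gene.

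**Figure D3:**
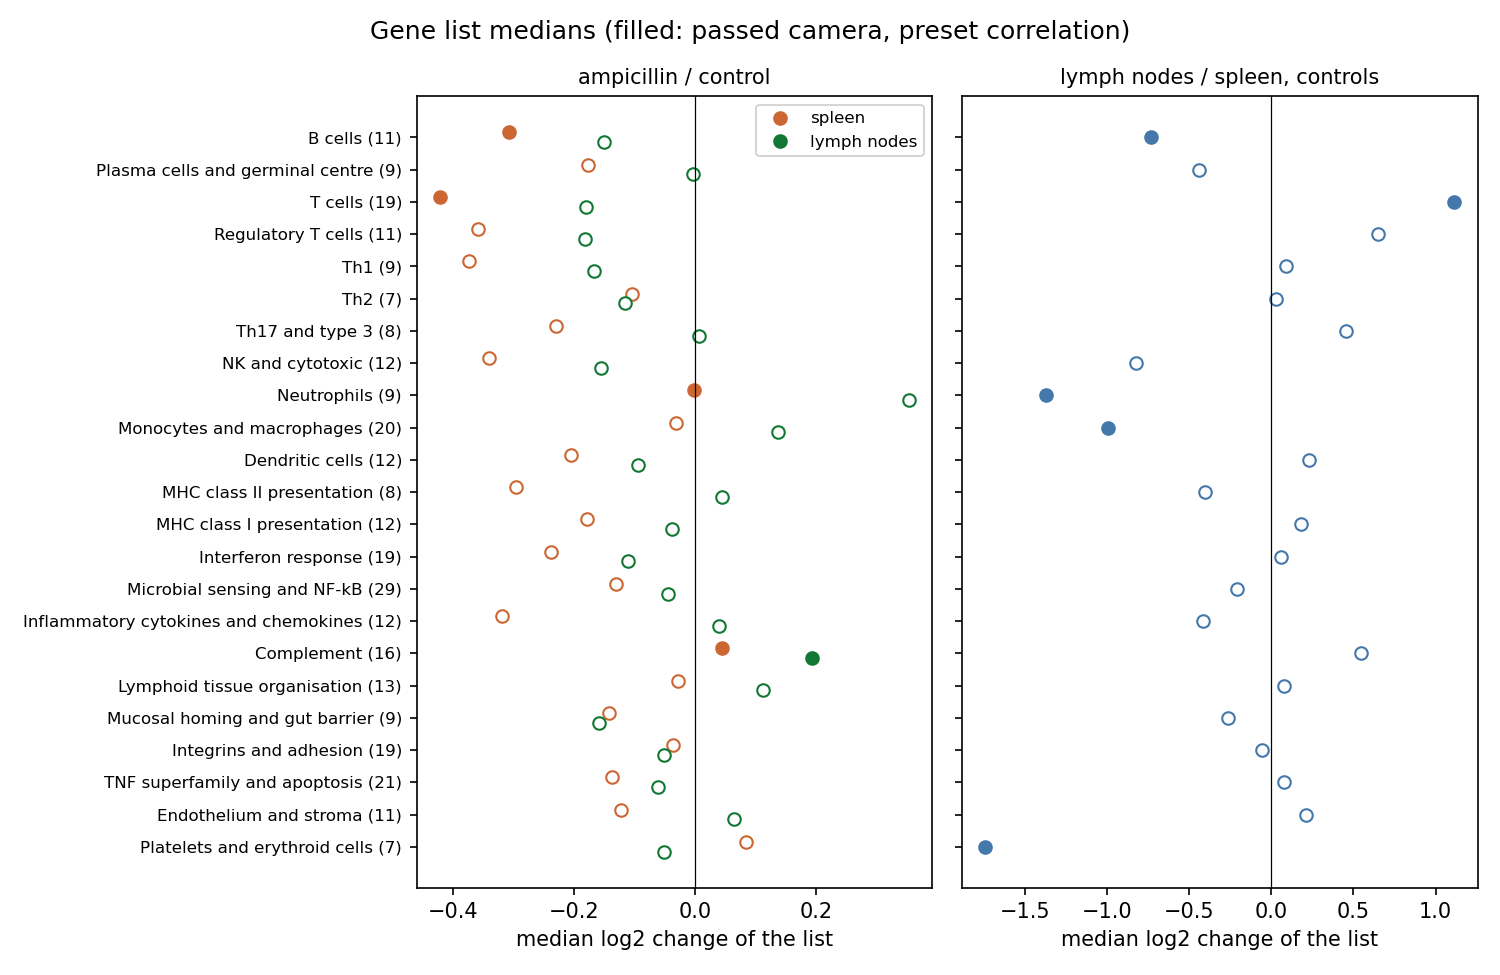
Median log2 change of each of 23 gene lists (number of tested genes in parentheses): left, ampicillin over control in spleen (orange) and lymph nodes (green); right, lymph nodes over spleen in controls. Filled points passed camera at the preset correlation; the T cell list lies at -0.42 in ampicillin spleen and at 1.11 in lymph nodes over spleen.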

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

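The list of MHC class II genes stood apart from the other genes in the test of the difference between the ampicillin effects of the tissues, but not against no change (fry adjusted p = 0.395). The median log2 difference over the 8 tested genes, lymph nodes minus spleen, was 0.33, which is 0.20 relative to the median of all tested genes, and all 8 lay above 0. So did 11 of 11 B cell genes (median 0.16), 11 of 11 regulatory T cell genes (median 0.21) and 17 of 19 T cell genes (median 0.23), lists that did not pass (camera adjusted p = 0.30, 0.58 and 0.30). The median of all tested genes was itself 0.13, and relative to it these 3 lists lay at 0.03, 0.08 and 0.10. B cells carry MHC class II, and their list had a median of -0.31 in ampicillin spleen. The MHC class II list passed with housekeeping scaling (camera adjusted p = 0.042; adjusted p = 0.98 with an estimated correlation) and with TMM scaling (adjusted p = 0.031). H2-Aa differed by 0.36 ± 0.14, H2-Ab1 by 0.36 ± 0.13 and H2-DMa by 0.36 ± 0.13 (SE), none past the test over all genes. No list passed camera without ampicillin spleen 2, ampicillin nodes 2 or 3, control spleen 1 or control node 3.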

How the results depend on the processing

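TMM, no scaling, DESeq2, limma in place of the count test and leaving out ampicillin spleens 2 and 3 together were chosen after seeing the data. The planned housekeeping recentring, count model and value table had become the main analysis. The cause of each shift below was not tested. In spleen, the count of 75 became 22 with TMM, 15 with median scaling, 15 with quantile normalization, 7 without scaling and 44 with limma without trend. It became 183 with sample weights, 0 with the 6 spleens alone, 0 with the methods' t-test after Benjamini-Hochberg and 6 without ampicillin spleens 2 and 3 together, where the lone sample is assumed to vary like the other groups. In nodes, the count of 2 became 32 with TMM, 19 with median scaling, 20 with quantile normalization, 0 without scaling, 47 with sample weights and 15 with the 6 node samples alone. It became 44 and 22 with DESeq2 with its own and with housekeeping size factors, 36 and 38 with the methods' t-test at its stated threshold on log2 and linear values, and 33 without those 2 spleens. At that threshold the methods' t-test called 52 genes in spleen on log2 values and 51 on linear values, and after Benjamini-Hochberg 2 in nodes. The difference of effects went from 0 to 57 genes with sample weights, 7 without scaling and 1 without those 2 spleens. The mean over tissues moved from 102 to 176 with sample weights, 59 with a fold minimum of 1.25, 44 without scaling and 37 without those 2 spleens. The tissue count moved from 285 to 177 without scaling. Within a tissue or treatment, deviations of same-numbered samples had correlations from -0.38 to 0.24. Control spleens 1 and 3 were closest to the control node of their own number (0.20 and 0.18), and no other sample matched its own number. With 3 samples per group this cannot show whether the numbers pair samples. They were not used as pairs because the labels name different mice. With the number as a replicate block the counts were 0 in spleen, 0 in nodes and 42 for the mean, and 2 lists passed in spleen, 4 in nodes and 0 for the difference.

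Lists passing in spleen, 4, became 2 with TMM, median scaling, quantile normalization, no scaling or the stricter filter of 80, 0 with an estimated correlation and 8 with fry. In nodes, 1 became 2 without scaling or with the stricter filter. It became 0 without a filter, with limma, limma without trend, pseudocount 2, an estimated correlation or fry. For the difference, 1 became 0 with the stricter filter, limma with pseudocounts 1, 2 and 10, limma without trend, quantile normalization, an estimated correlation or fry. For the tissues, 5 became 0 with an estimated correlation and 12 with fry. The correlation of effects, 0.27, was 0.31 with the stricter filter, 0.31 with pseudocount 10 and 0.22 without a filter. Leaving out 1 sample at a time gave 0 to 159 genes in spleen, 0 to 32 in nodes, 0 to 59 for the difference, 67 to 157 for the mean and 265 to 305 for the tissues. It gave 1 to 6 lists in spleen, 0 to 4 in nodes, 0 to 3 for the difference and 5 to 5 for the tissues, and a correlation of 0.22 to 0.30. Over these fits Camp in spleen ran from -1.16 to 0.014 and Cfd in spleen from -0.21 to 2.02. Cd9 in nodes was -0.010 without scaling. None of these 3 had passed. Over all settings, calls of named genes were lost in 272 of 717 values in spleen, 11 of 551 in nodes, 4 of 644 for the tissues and 0 of 240 for the mean. Calls were gained in 56 of 551 values in nodes, 9 of 191 for the difference and 4 of 717 in spleen.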

Other observations

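Members of further lists fell in the ampicillin spleen, described here with genes chosen after their values were seen. Of 12 tested genes for MHC class I presentation 4 fell, and 4 when adjusted over the list alone. They were the peptide transporter gene Tap1, by 0.56, H2-K1 by 0.46, the immunoproteasome gene Psmb9 by 0.44 and Cd1d1 by 0.40 (log2, edgeR). Of 12 dendritic cell genes 4 fell, Xcr1, Cd40, Itgax and Irf8, and of 19 interferon response genes 3 fell, among them Stat2 by 0.48 and Irf1 by 0.50, with the same counts over each list alone. None of these 3 lists passed relative to the panel (camera adjusted p = 0.77, 0.61 and 0.64), and with TMM scaling 1, 0 and 1 of their members fell. In untreated mice, 6 of 12 genes of natural killer and cytotoxic cells were lower in lymph nodes than in spleen and 1 was higher, with Gzma at -2.78 and Cd244 at least 3.29-fold lower. Of 16 complement genes 10 were higher and 3 lower, with C3 at 1.20. Neither list passed (camera adjusted p = 0.20 and 0.13).

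The tests of the 3 patterns below were chosen after the patterns were seen. The counts of sample splits and relabellings were planned. In the erythroid pattern, Tfrc, Tal1, Icam4 and Abcb10 were high in ampicillin spleens 2 and 3. Scaling is argued against as its source, since the lowest median change over 5 scalings was 1.83 (log2). Blood left in the tissue stays open. The median level of 5 platelet and neutrophil transcripts (Ppbp, Gp1bb, S100a8, S100a9 and Camp) differed by -0.40 between ampicillin and control spleens (SD within groups 0.67), but at a median of 3760 scaled counts in controls it could hide a small share of blood. An ampicillin effect stays open too, because 2 of the 3 ampicillin spleens lay above all controls and the other below them (mean difference 1.62, exact permutation p = 0.4, two-sided, with 0.1 the smallest possible).

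The second pattern is the excess of falls in the ampicillin spleen, 65 of 75 calls. With TMM 50% of calls were falls, but TMM put the median of all tested genes at 0.00063, which by itself makes rises and falls nearly even, so this does not decide whether housekeeping scaling is the source. With TMM 13 of the 14 housekeeping genes were higher in ampicillin spleens, at a median of 0.17, which is the same shift seen from the other side. Whether housekeeping genes rose or immune genes fell cannot be read from relative counts, and an effect of ampicillin stays open, as untested.

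The third pattern is the lower T cell list in the ampicillin spleen, which relative to all tested genes within a library differed by -0.27 (SD within groups 0.20, exact permutation p = 0.3). Housekeeping scaling divides all genes of a library by a single factor, which nearly cancels in this measure. The factor can therefore hardly be the source of this relative difference, whatever its size. The list's own median does depend on the factor, at -0.42 with housekeeping and -0.26 with TMM scaling. Dilution by erythroid cells stays open. The T cell list differed by -0.37 relative to the monocyte and macrophage list (SD within groups 0.17, exact permutation p = 0.1, the smallest possible). Part of that lay in the monocyte and macrophage list. It stood at 0.48, 0.48 and 0.35 above the panel mean in ampicillin spleens 1, 2 and 3, and 0.30 to 0.35 in controls. Whether dilution would move both lists alike was not tested. Glucocorticoid exposure, which Fkbp5 might point to, stays open, with 6 other induced genes (Nfkbia, Cxcr4, Il1r2, Cd163, Il6ra and Tlr2) differing by 0.10 relative to all tested genes (SD within groups 0.12, exact permutation p = 0.4). An effect of ampicillin on T cells stays open, untested apart from the comparison of groups.

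For the mean over tissues, 1 of 100 splits of the samples, the real one, gave as many genes (102, highest other 2), so a chance split is an unlikely source of that count. The splits cannot tell ampicillin from any other difference between the treated and the untreated mice. For the difference of effects, 100 of 100 splits gave as many genes (0, highest other 0), which a real count of 0 makes certain, so it says nothing about chance. The 10 splits of 3 against 3 are too few for a share under 0.05. In spleen the real split called 75 genes and the highest other 10, with 1 split as large. In nodes the real split called 2 and the highest other 2, with 2 splits as large, and between tissues 285 and 0, with 1 split as large. For the correlation of effects, 2 of 100 relabellings, the real one among them, gave a Pearson correlation as large as 0.27. The highest other, 0.28, lay above the real value. Chance is thus unlikely at the 0.05 level but not excluded.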
